A study of Mus musculus with 24 samples.

How the data were processed

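RNA-seq was done on aortic tissue of 24 mice in 4 groups: wild type (WT) on plain water, 6 libraries, WT on β-aminopropionitrile (BAPN), 7, ATAD3A knock-in (KI) on plain water, 5, and KI on BAPN, 6. Per the labels' protocols, males aged 3 weeks drank BAPN, an inhibitor of lysyl oxidase, at 0.5% (w/v) for 28 days, and poly(A) RNA was taken from the ascending aorta down to the abdominal bifurcation. The deposited table holds read counts per gene, not normalized, made by the authors. Per the submitters' processing notes the tools were Trim Galore, FastQC, HISAT2 and DESeq2 and the builds GRCm38 and mm10. The read counter, the strand setting and the tool versions are not given in the sources used here. The 24 count columns were matched to samples by the codes in the labels, and 0 per-sample columns were left unmatched. No row lacked a gene. Of 21959 genes, 21851 had an identifier in the GENCODE M21 annotation of GRCm38 and 21723 were protein coding there. Only 514 of these had the start and end of that annotation, so coordinates are printed as the deposited table gives them and their build is open. Totals ran from 13127645 to 26490651 counts per library, and 2577 genes had no read in any library. Without strand information, reads of overlapping and antisense genes cannot be told apart.

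From the deposited counts, edgeR 4.0.16 in R 4.3.3 fitted 1 mean per group over all 24 libraries, with TMM factors, the filter of filterByExpr by group and robust quasi-likelihood F tests. This left 14216 genes tested. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, with no minimum fold. CPM values, counts scaled to a common library total, use the TMM factors. The comparisons were BAPN within each genotype, genotype within each treatment, and their interaction. The 36 gene lists, the tests and the rule for named genes were set before the data were examined. The rule takes Atad3a, the 8 largest rises and the 8 largest falls past the threshold, and up to 4 members with the smallest adjusted p of each list described. A rise or fall needed at least 5 CPM in the higher group. It also needed every library of the BAPN group, or of the KI group between genotypes, beyond the other group's mean. The libraries of the other group were not checked singly, so 1 high library can set that mean. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. A list is said to be called by its value at the preset. The estimated correlations ran from 0.0998 (clock genes, BAPN in WT) to 0.894 (B cell markers, BAPN in WT), all above the preset. Adjusted p at the preset can therefore be far too small. A list needed 5 tested members, which left out neutrophil markers with 4. A list score is the mean log2 CPM of its genes with a prior count of 2. Scores and Atad3a CPM were compared with exact two-sided permutation tests. Annotated terms of the deposited table with 15 to 300 tested genes were tested with camera as well. Some genes that the rule takes are not reported here. Another 4 marker lists (airway epithelium, sympathetic neuron, mesothelium, heat shock proteins) were chosen after the data were seen.

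The alternatives were other size factors, DESeq2 1.42.0, limma voom with quality weights, 2 other filters, only the groups compared, the replicate number as a block, no robust estimation, fat and muscle scores as covariates, 2 other thresholds and each library left out. Added after the data were seen were edgeR's newer quasi-likelihood method, the mesothelium score as a covariate, offsets for gene length (alone, and together with leaving out WT replicate 5), and a fit without the 4 libraries over 5 scaled median absolute deviations in an other-tissue score (WT replicate 5, KI replicates 1, 2 and 5). Without these 4 libraries only KI replicates 3 and 4 remain in KI on plain water, so a call lost there can come from fewer samples. The covariates were the scores of the adipocyte, skeletal muscle and cardiac muscle lists themselves. A loss of the calls of these lists with covariates was therefore built in. Each animal is taken as 1 sample, since the labels list them as separate samples. No pair of libraries held identical counts, and the smallest chi-square per degree of freedom between libraries of 1 group was 30.8.

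The steps were tested on simulated data with 200 changed genes among 14216. For BAPN in WT, 51 of 100 genes changed by 1 log2 unit and 84 of 100 changed by 2 were recovered, with 9 false calls. For BAPN in KI these were 44 and 82 of 100, with 6 false calls. For KI against WT on plain water they were 54 and 71 of 100, with 6 false calls, and on BAPN 49 and 75 of 100, with 7. For the interaction they were 17 and 75 of 100, with 6. These simulations draw genes independently, unlike tissue. Figures were drawn with matplotlib.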

Results

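Polyadenylated RNA of whole aortas was counted in 24 male mice to compare wild type (WT) with ATAD3A knock-in (KI) animals, with and without BAPN, which blocks collagen and elastin cross-linking and induces aortic aneurysm and dissection. There were 6 WT, 7 WT-BAPN, 5 KI and 6 KI-BAPN libraries of 13127645 to 26490651 counts. Mitochondrially encoded genes took 4.24 to 14.8% of the counts.

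Atad3a, which encodes an AAA ATPase of the mitochondrial inner membrane, was higher in every KI library than in every WT library. Its level was 1079 ± 407 CPM (SD, n = 5) in KI and 40.2 ± 11.4 CPM (SD, n = 6) in WT, a ratio of 26.8 (exact two-sided permutation p = 0.00216). On BAPN it was 587 ± 262 CPM (SD, n = 6) in KI and 33.2 ± 7.25 CPM (SD, n = 7) in WT, a ratio of 17.7 (exact permutation p = 0.000583). The log2 differences were 4.75 ± 0.33 (SE) and 4.14 ± 0.30, with edgeR adjusted p of 7.33e-09 and 1.37e-08. Within KI, the BAPN group had 0.544 of the level on plain water (exact permutation p = 0.0390, 0.0519 after Benjamini-Hochberg adjustment over 4 tests, edgeR adjusted p = 0.273). In the deposited table the gene, ENSMUSG00000029036, lies on chromosome 4 from 155825098 to 155845550, in coordinates whose build is open. The labels do not describe the knock-in allele, and the counts cannot separate its transcripts from those of the endogenous gene.

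**Figure D1:**
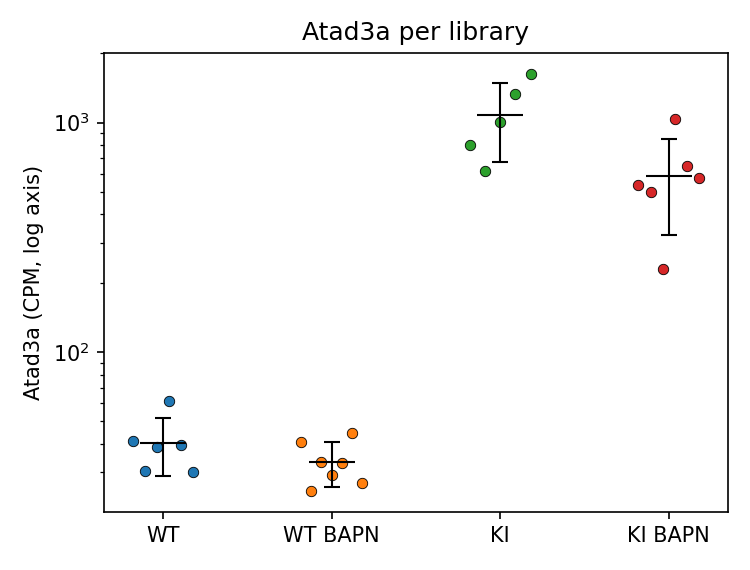
Atad3a in CPM (log axis) for each library of the 4 groups. Points are libraries and bars are the mean and SD. The KI libraries lie between 617 and 1629 CPM and the KI-BAPN libraries between 231 and 1038 CPM, all above the highest WT library at 61.4 CPM.

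The first comparison asked what BAPN changed in the WT aorta. Cell cycle genes rose on BAPN, and so did part of the collagen genes. Of 22 tested cell cycle genes 13 rose and none fell over all genes tested, and 19 rose adjusted over the list alone, with a median log2 change of 2.42. The list had a camera adjusted p of 9.78e-12, and an adjusted p = 0.525 with an estimated correlation. The cyclins Ccnb2 (log2 change 2.87 ± 0.63) and Ccna2 (2.81 ± 0.62), the kinase Cdk1 (2.94 ± 0.71) and Cdc20 (2.46 ± 0.58), an activator of the anaphase-promoting complex, were among them. The largest rises that met the naming rule were Cthrc1, a secreted protein of injured arteries, from 1.34 ± 0.709 CPM (SD, n = 6) to 22.5 ± 36.2 CPM (SD, n = 7), and the mitotic genes Pbk (log2 3.77 ± 0.88), Hmmr (3.66 ± 0.80), Iqgap3 (3.42 ± 0.68), Ube2c (3.30 ± 0.78), Ccnb1 (3.30 ± 0.81), Cenpe (3.22 ± 0.79) and Cdkn3 (3.20 ± 0.80). Their edgeR adjusted p lay between 0.0122 and 0.0274. Cthrc1, Ccnb1 and Cdkn3 lost their call without WT replicate 1 or 4 and Cenpe without WT replicate 1 (edgeR adjusted p of 0.0504 to 0.0602), at log2 changes of 3.08 to 3.97. Without WT-BAPN replicate 5 Cthrc1 was at 2.76 (edgeR adjusted p = 0.0789).

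Of 26 collagen and fibrosis genes 5 rose on BAPN in WT and none fell, and 14 rose adjusted over the list alone. The median log2 change was 0.92 (camera adjusted p = 1.48e-07, adjusted p = 0.525 with an estimated correlation, fry adjusted p = 0.0259). Examples were Col5a2 (1.16 ± 0.27), Col6a3 (1.09 ± 0.29), Cthrc1 (4.05 ± 1.04) and Spp1, which encodes osteopontin (6.03 ± 1.58). Of 21 elastic fibre genes 1 rose, Mfap2 (0.95 ± 0.25), also adjusted over the list alone, and the value of Eln, elastin, was 1.86 ± 0.61 (edgeR adjusted p = 0.0654). The elastic fibre list had a camera adjusted p of 0.000158, and an adjusted p = 0.525 with an estimated correlation and 0.303 with tissue scores as covariates. Of 20 matrix protease genes 1 rose, also 1 adjusted over the list alone, and the list with a median of 0.20 was not called (camera adjusted p = 0.295).

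Of 20 contractile smooth muscle genes 3 fell on BAPN in WT, among them Des (-2.79 ± 0.61) and Tagln (-1.06 ± 0.29), and 4 fell adjusted over the list alone. The camera adjusted p was 7.8e-05, and the adjusted p = 0.618 with an estimated correlation. Of 17 mitochondrial proteostasis genes 3 fell, the chaperonins Hspe1 (-1.46 ± 0.29) and Hspd1 (-1.19 ± 0.27) and the protease subunit Clpp (-0.68 ± 0.19), and 5 adjusted over the list alone. Of 20 immediate early genes 4 fell, among them Ier2 (-1.02 ± 0.28) and the heat shock gene Hspa1a (-2.77 ± 0.80), and 9 adjusted over the list alone. These 2 lists had camera adjusted p of 5.11e-05 and 6.15e-06, and both an adjusted p = 0.525 with an estimated correlation. The heat shock score, from a list chosen after the data were seen, was 7.83 to 9.25 in the WT libraries on plain water and 6.36 to 8.18 in the other 18, KI on plain water included. The labels give no time, day or batch of collection. Of 24 autophagy genes 3 fell, Sqstm1 (-0.57 ± 0.15), Map1lc3a (-0.84 ± 0.24) and Pink1 (-0.67 ± 0.19), and 4 adjusted over the list alone (camera adjusted p = 0.00467, adjusted p = 0.606 with an estimated correlation). None of 69 nuclear encoded and none of 13 mitochondrially encoded oxidative phosphorylation (OXPHOS) genes passed singly or adjusted over the list alone, with medians of -0.35 and -0.84. Their camera adjusted p were 1.48e-07 and 1.91e-06, and the adjusted p = 0.814 and 0.525 with an estimated correlation.

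The 8 largest falls by the naming rule were genes of airway and gland epithelium: Bpifa1 (log2 change -11.45 ± 2.28), Cyp2a5 (-11.35), Scgb3a2 (-10.31), Scgb1a1 (-10.27), Ltf (-10.12), Reg3g (-9.93), Scgb3a1 (-9.57) and Bpifb1 (-9.07). Their levels were highest in 1 library: Bpifa1 was at 9680 CPM in WT replicate 5 and at 1.57 to 41.3 CPM in the other WT libraries. Without that library the log2 changes lay between -4.63 and -2.66, and 6 of the 8 genes were still called, all but Scgb3a2 (edgeR adjusted p = 0.0612) and Reg3g (0.158). The airway score, from a list chosen after the data were seen, was 0.58 to 3.58 in the other WT libraries, -0.99 to 1.03 on BAPN in WT and -0.78 to 4.01 in KI on plain water. The same library held skeletal muscle RNA, with Acta1 at 1976 CPM against 0.342 to 4.79 CPM in the other WT libraries. Of 11 skeletal muscle markers 9 fell, the same number adjusted over the list alone (camera adjusted p = 0.0306, adjusted p = 0.814 with an estimated correlation). Of 12 Schwann cell markers 3 fell, among them Mbp (-3.35 ± 0.95) and Ncmap (-3.47 ± 0.99), and 11 adjusted over the list alone (camera adjusted p = 9.96e-05, adjusted p = 0.618 with an estimated correlation). The Schwann score of that library was 5.28 on the log2 scale, against a median of 1.52 over all libraries. The skeletal muscle list had a camera adjusted p of 0.344 without WT replicate 5, 0.0586 and 0.0644 without WT-BAPN replicates 1 and 7, 0.0810 with the mesothelium score as a covariate and 0.896 with fat and muscle scores as covariates, where the Schwann list had 0.0867. The skeletal muscle score is itself among the fat and muscle covariates, so the loss of that list's call with them was built in.

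In all, edgeR called 873 of 14216 genes for BAPN in WT, 489 higher and 384 lower, and 6 genes at an adjusted p of 0.01, while DESeq2 called 1493 and limma voom 4234. The count was 327 without WT replicate 1, 404 without WT replicate 4, and 503, 375, 420, 351, 442 and 1609 without WT-BAPN replicates 2 to 7. Without WT replicate 5 it was 1107, and without all 4 libraries rich in other tissue 1524.

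**Figure D2:**
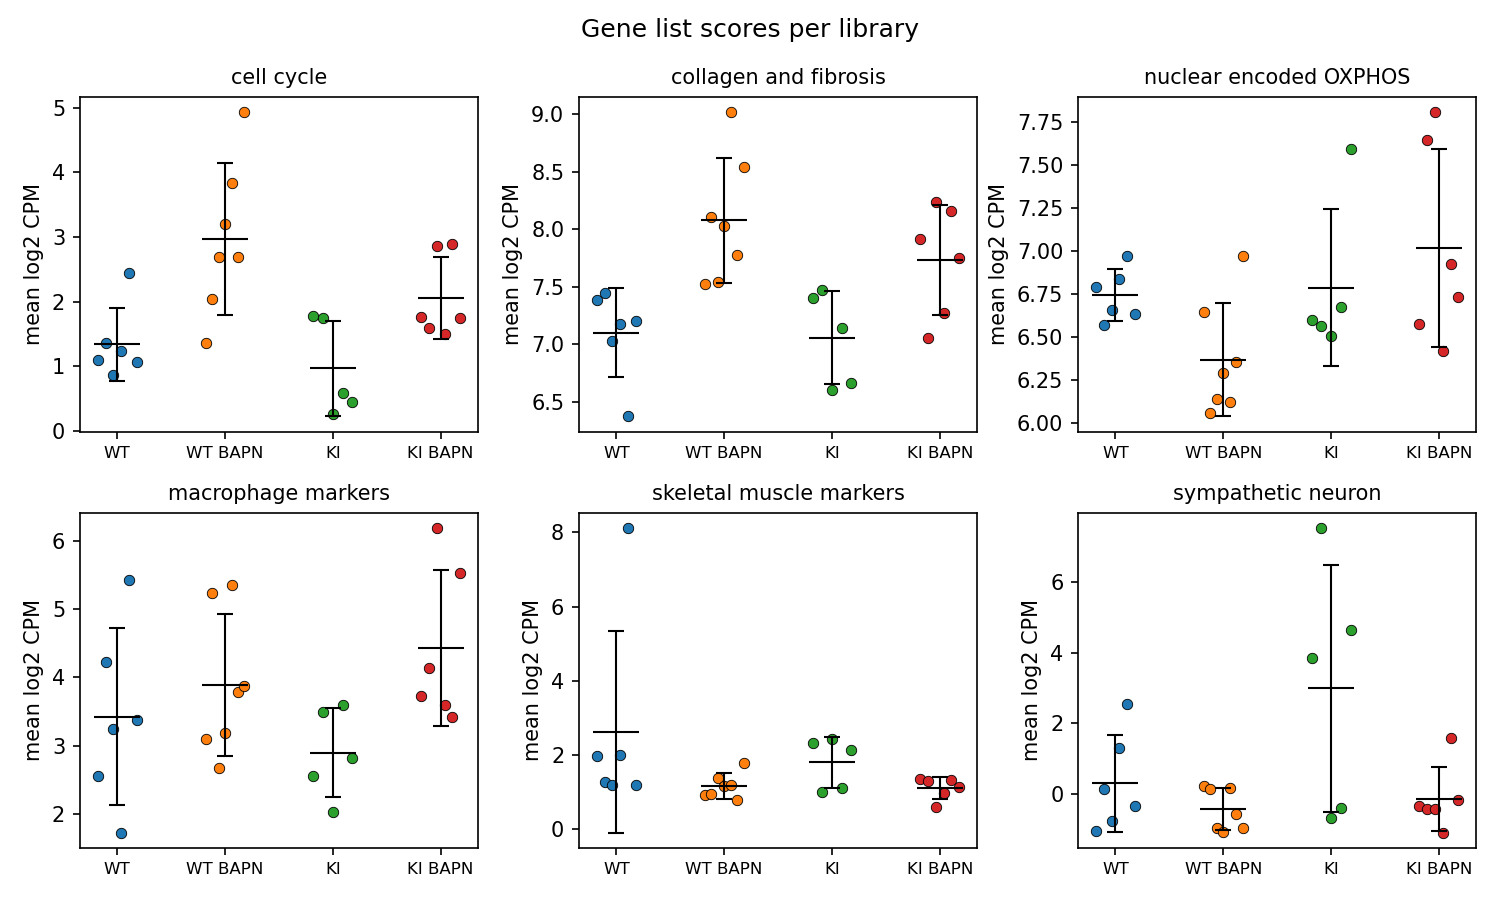
Mean log2 CPM of 6 gene lists in each library of the 4 groups. Points are libraries and bars are the mean and SD. The sympathetic neuron list was chosen after the data were seen. Skeletal muscle stands out in 1 WT library at 8.11, and sympathetic neuron genes in KI libraries at 3.86, 4.64 and 7.54.

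The second comparison asked what BAPN changed in the KI aorta. It called 5 genes. Ces2g, a carboxylesterase, rose from 14.5 ± 3.20 CPM (SD, n = 5) to 26.4 ± 4.02 CPM (SD, n = 6) (log2 0.87 ± 0.16). Rab3b (-5.25 ± 0.91), the vesicular monoamine transporter Slc18a2 (-4.25 ± 0.77), the synapsin Syn2 (-3.32 ± 0.58) and Omp (-5.41 ± 0.95) fell. Omp lay outside the naming rule and was chosen after its values were seen, as the count is small. The edgeR adjusted p of all 5 was 0.0375. Syn2 was at 129 CPM in KI replicate 2 and 33.4 CPM in KI replicate 5, and at 8.14 to 9.63 CPM in the other KI libraries. The sympathetic neuron score was over 5 scaled median absolute deviations above the median in KI replicates 1, 2 and 5.

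Among lists on BAPN in KI, none of 20 macrophage markers passed over all genes tested, and 15 rose adjusted over the list alone, with a median log2 change of 2.12 (camera adjusted p = 2.71e-11, adjusted p = 0.395 with an estimated correlation). Values were 3.12 ± 0.94 for Trem2, 2.44 ± 0.78 for C1qc and 2.47 ± 0.79 for C1qa. The macrophage score, 4.43 ± 1.15 (SD, n = 6) against 2.90 ± 0.651 (SD, n = 5), had an exact permutation p of 0.0281, and 0.422 after adjustment over 52 tests. The mesothelium score, from a list chosen after the data were seen, was 4.09, 3.10 and 2.19 in KI-BAPN replicates 3, 6 and 2, which had the highest macrophage scores of their group at 6.19, 5.53 and 4.13. It was -2.32 to -1.54 in the other 3, with macrophage scores of 3.42 to 3.73. With it as a covariate camera still called macrophage (adjusted p = 1.79e-14), cytokine (3.10e-07) and fibroblast genes (7.70e-08). Of 24 inflammatory cytokine and adhesion genes none passed over all genes, and 9 rose and 1 fell adjusted over the list alone, with Ccl8 at 4.07 ± 1.21 and the inhibitor Nfkbia at -1.04 ± 0.31 (camera adjusted p = 2.13e-08, adjusted p = 0.440 with an estimated correlation). Of 14 adventitial fibroblast markers none passed over all genes and 4 rose adjusted over the list alone, among them Cd248 (1.08 ± 0.30), Clec3b (1.55 ± 0.50) and Lum (2.04 ± 0.68). For fibroblasts the camera adjusted p was 1.56e-08, and the adjusted p = 0.395 with an estimated correlation and 0.0763 without the 4 libraries rich in other tissue. No cell cycle gene passed either way, the median over 22 genes being 1.06 (camera adjusted p = 5.18e-09, adjusted p = 0.543 with an estimated correlation).

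Further lists stood above the other genes by camera on BAPN in KI: collagen (median 0.56), matrix proteases (0.64), clock genes (0.38), elastic fibre (0.31), cardiac muscle (1.51), erythroid markers (2.42), nuclear OXPHOS (0.28), interferon (0.53) and lysosome genes (0.07). Contractile (-0.40), Schwann cell (-1.52) and immediate early genes (-0.37) stood below. Camera adjusted p ran from 1.25e-05 for nuclear OXPHOS to 0.0467 for lysosome genes, and the adjusted p = 0.395 to 0.831 with an estimated correlation. No member passed over all genes tested. Adjusted over the list alone 5 clock, 3 cardiac, 2 elastic fibre and 2 protease genes rose, and of erythroid markers 4 rose and 1 fell. The Schwann score was 4.50 in KI replicate 5 and 3.58 in KI replicate 2, and the camera adjusted p of that list was 0.150 without KI replicate 5, 0.0581 without KI-BAPN replicate 4 and 0.964 without the 4 libraries rich in other tissue. Without KI replicate 5 elastic fibre genes had 0.150, and without KI replicate 3 contractile genes 0.0524. Interferon genes had 0.0625, 0.118 and 0.208 without KI replicates 1 and 3 and KI-BAPN replicate 3, and nuclear OXPHOS 0.0631 and 0.0892 without KI-BAPN replicates 2 and 3. Immediate early genes had 0.0672 to 0.0959 without KI replicates 4 and 5 and KI-BAPN replicates 2 and 3. Clock genes had 0.0873 without KI-BAPN replicate 4 and erythroid markers 0.0514 without KI-BAPN replicate 3. Lysosome genes were not called without any 1 of 7 libraries (0.0567 to 0.358, highest without KI replicate 2). Without the 4 libraries the elastic fibre, protease, clock, interferon and lysosome calls ended too (0.0843 to 0.580), and with fat and muscle covariates those of contractile, clock, erythroid, interferon and cardiac genes (0.181 to 0.747). Only KI replicates 3 and 4 are left in KI on plain water without the 4 libraries, so fewer samples can end a call too. The cardiac muscle score is itself among the covariates, so the loss of the cardiac call was built in. With the mesothelium score as a covariate interferon genes had 0.342.

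The count of 5 was 0 without KI replicate 2 or 5, and 140 and 143, all 5 included, without KI replicates 3 and 4. It was 1 without KI-BAPN replicate 2, a gene outside the 5, and 0 without any other KI-BAPN library. With the mesothelium score as a covariate it was 3, where Ces2g (0.86) and Slc18a2 (-4.11) had an edgeR adjusted p of 0.0674. With the replicate number as a block edgeR called 0, and DESeq2 called 198.

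The third comparison set KI against WT on plain water. Beside Atad3a, the genes that met the rule and were higher in KI were Syn2 (2.76 ± 0.56), the clock transcription factor Npas2 (2.43 ± 0.49), Zc3h6 (1.62 ± 0.30), the synaptic vesicle protein Sv2a (1.29 ± 0.27), Acy3 (1.05 ± 0.22), Mmab (0.98 ± 0.20), of cobalamin metabolism, and Epm2a (0.83 ± 0.15), which encodes laforin. Lower in KI were the hyaluronan receptor Cd44 (-1.57 ± 0.33), Hspa4l (-1.43 ± 0.29), the sphingosine kinase Sphk1 (-1.35 ± 0.27), Baiap2l1 (-1.26 ± 0.25), Ablim1 (-1.20 ± 0.18), the actin nucleator Spire1 (-1.12 ± 0.23), Sgms2 (-1.06 ± 0.21) and the hedgehog effector Gli3 (-0.995 ± 0.18). Ablim1 was at 253 to 294 CPM in the WT libraries and at 104 to 136 CPM in the KI libraries. In WT on BAPN it was also low, at 144 ± 45.6 CPM (SD, n = 7). The edgeR adjusted p was 0.00884 for Ablim1 and between 0.0311 and 0.0425 for the others. The sympathetic neuron score was 7.54 in KI replicate 2, where Syn2 was at 129 CPM and Sv2a at 51.5 CPM. Without that library Syn2 was at 1.42 (edgeR adjusted p = 0.274) and Sv2a at 0.91 (0.241), and none of these 15 genes passed the test. The other 13 had log2 differences of 0.77 to 2.25 and -1.67 to -1.01 there, against 0.83 to 2.43 and -1.57 to -0.995 with it. Of the 15, 12, 10, 1 and 11 lost their call without KI replicates 1, 3, 4 and 5, 14 without any 1 of WT replicates 1 to 4, and 12 without WT replicate 6.

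Of 17 clock genes 1 rose in KI on plain water, Npas2, and adjusted over the list alone 2 rose and 8 fell, with Dbp at -1.47 ± 0.46 and Arntl at 1.20 ± 0.38 (camera adjusted p = 0.00528, adjusted p = 0.784 with an estimated correlation). The clock score was 4.81 to 5.38 in the WT libraries and 4.58 to 5.69 in the other 18. Its members moved both ways, so this mean can hide a shift and the overlap of the ranges decides nothing. As no label gives a time of day, collection day or batch, a batch and the group cannot be told apart. No immediate early gene of 20 (median -0.55) and no cytokine gene of 24 passed either way. For these lists camera adjusted p were 0.000165 and 0.00462, and the adjusted p = 0.784 with an estimated correlation for both. No T cell marker passed over all genes, and all 10 tested fell adjusted over the list alone (camera adjusted p = 0.0259, adjusted p = 0.784 with an estimated correlation). WT replicate 5 held T cell RNA at a score of 4.87, against a median of -1.39 over all libraries. Adventitial fibroblast (median -0.80), TGF-beta (-0.23), cardiac muscle (-2.35), mitochondrially encoded OXPHOS (-0.45), macrophage (-1.17) and interferon genes (-0.54) stood below the other genes too. Camera gave adjusted p from 0.00462 to 0.0329, and the adjusted p = 0.784 with an estimated correlation. Adjusted over the list alone 3 TGF-beta and 2 cardiac genes fell. WT replicate 5 had the highest macrophage (5.43), interferon (4.84) and cardiac muscle (3.90) scores of its group. Without it camera no longer called T cell (adjusted p = 0.737), interferon (0.496), macrophage (0.339), cardiac muscle or cytokine genes (0.0735 for both). Interferon genes had 0.0663, 0.0729 and 0.108 without WT replicate 2 and KI replicates 1 and 3, macrophage markers 0.0605 and 0.0720 without WT replicate 2 and KI replicate 3, and mitochondrially encoded OXPHOS 0.0587 without WT replicate 1. Of these 10 lists, immediate early and mitochondrially encoded OXPHOS genes were still called without the 4 libraries rich in other tissue (the others 0.0502 to 0.486), and with covariates TGF-beta genes as well (the others 0.0541 to 0.988). The cardiac muscle score is itself among the covariates, so the loss of the cardiac call with them was built in. With the mesothelium score as a covariate T cell, macrophage and interferon genes had 0.0539, 0.0606 and 0.100. Of 69 nuclear OXPHOS genes none passed, with a median of 0.11.

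For KI against WT on plain water edgeR called 27 genes, 14 higher and 13 lower, and DESeq2 480. The count was 2, 3, 2, 2, 293 and 6 without WT replicates 1 to 6, and 5, 1, 63 and 6 without KI replicates 1, 2, 4 and 5. Without the 4 libraries rich in other tissue it was 1, and with the mesothelium score as a covariate 73. Leaving out the 4 kept only KI replicates 3 and 4, and the 15 genes named above beside Atad3a lost their call. Those lower in KI had log2 differences of -1.44 to -0.93 there, against -1.57 to -0.995 with all libraries. Syn2 and Sv2a were at 0.70 and 0.99, and the others higher in KI at 0.70 to 2.18, against 0.83 to 2.43. The lost calls can thus reflect the smaller group as well as other tissue.

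The fourth comparison set KI against WT on BAPN, and Atad3a was the 1 gene called by edgeR. OXPHOS genes had higher values in KI as a list: none of 69 nuclear encoded genes passed over all genes tested and 58 rose adjusted over the list alone, with a median log2 difference of 0.71 (camera adjusted p = 4e-37, adjusted p = 0.686 with an estimated correlation). Examples are Atp5l (0.90 ± 0.22), Ndufb9 (1.43 ± 0.37) and Ndufa5 (1.03 ± 0.27). Of 19 fatty acid oxidation genes none passed over all genes and 5 rose adjusted over the list alone, with Hadh at 1.04 ± 0.34 and Etfb at 2.05 ± 0.69 (camera adjusted p = 1.29e-05, adjusted p = 0.686 with an estimated correlation). The median was 0.45 over 14 genes of the TCA cycle, 0.26 over 22 genes of lipoylation and lipoylated complexes, and 0.31 over 20 genes of mitochondrial fatty acid synthesis and iron-sulfur assembly, where none passed either way. Their camera adjusted p were 1.96e-05, 0.00817 and 3.29e-05, and the adjusted p = 0.686 with an estimated correlation. Without KI-BAPN replicate 2 or 3 lipoylation had a camera adjusted p of 0.0526 and 0.0517. In these libraries the TCA cycle score was 7.31 and 7.31, and the fatty acid oxidation score 6.44 and 6.50. In the other KI-BAPN libraries these scores were 6.05 to 6.41 and 4.93 to 5.38. In WT-BAPN they were 5.91 to 6.55 and 4.81 to 5.71. Lias, the lipoyl synthase, was at 0.34 ± 0.15 and Dbt, of a lipoylated complex, at 0.36 ± 0.13. Neither lysosome genes (median -0.04 over 42, camera adjusted p = 0.854) nor mitochondrial contact and dynamics genes (median 0.11 over 28, camera adjusted p = 0.0764) stood apart. Of 22 cell cycle genes none passed over all genes and 7 fell adjusted over the list alone, with Kif20a at -1.87 ± 0.53 and Tk1 at -0.92 ± 0.30 (camera adjusted p = 2.42e-07, adjusted p = 0.686 with an estimated correlation).

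Adipocyte markers were measured beside these lists. On BAPN the median difference between KI and WT was 1.37 over 14 white and 0.996 over 15 brown adipocyte markers, with Adipoq at 2.35 ± 0.92 and Cidea at 2.33 ± 0.70. None passed over all genes, 1 and 3 rose adjusted over the list alone, and the camera adjusted p were 1.96e-05 and 2.99e-05, with an adjusted p = 0.686 for both with an estimated correlation. The brown adipocyte score was 3.77 ± 0.690 (SD, n = 6) in KI and 2.69 ± 0.978 (SD, n = 7) in WT (exact permutation p = 0.0443, 0.458 after adjustment over 52 tests). Schwann cell (median 1.15), erythroid (0.999), macrophage (0.78), fibroblast (0.41), mitochondrially encoded OXPHOS (0.31) and mitochondrial proteostasis genes (0.13) stood above the other genes, and collagen (-0.47) and elastic fibre genes (-0.25) below. Camera gave these adjusted p from 0.00235 to 0.0379, and the adjusted p = 0.686 to 0.749 with an estimated correlation. The camera adjusted p of macrophage markers was 0.0731 to 0.350 without WT-BAPN replicates 1, 3 and 7 or KI-BAPN replicates 3 and 6. That of fibroblast markers was 0.0976 to 0.320 without WT-BAPN replicates 3 and 7 or KI-BAPN replicates 3 and 6. It was 0.0670 without the 4 libraries and 0.0846 with offsets for gene length. Elastic fibre genes had 0.0514 to 0.233 without WT-BAPN replicates 1, 5 and 7 or KI-BAPN replicates 2 and 4, and erythroid markers 0.0567 to 0.144 without WT-BAPN replicate 7 or KI-BAPN replicates 3 and 4. Proteostasis genes had 0.0842 and 0.103 without WT-BAPN replicate 2 and KI-BAPN replicate 2, Schwann markers 0.109 without KI-BAPN replicate 5 and collagen genes 0.0604 without KI-BAPN replicate 4. With tissue scores as covariates camera still called nuclear OXPHOS (median 0.41, adjusted p = 1.79e-19) and cell cycle genes (2.18e-05), and no longer the other 14 lists called here. Their adjusted p ran from 0.0950 to 0.885, with 0.840 for fatty acid oxidation, 0.234 for the TCA cycle, 0.0950 for mitochondrial fatty acid synthesis, 0.885 for lipoylation, 0.470 for brown and 0.458 for white adipocyte markers, whose direction turned. The adipocyte scores are themselves among the covariates, so the loss of the adipocyte calls was built in. The brown adipocyte list also shares Cpt1b with the fatty acid oxidation list. DESeq2 called 28 genes and limma voom 3.

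The fifth comparison asked whether the response to BAPN differed between genotypes. The edgeR interaction called 0 genes at an adjusted p under 0.05, with 2111 genes at an unadjusted p under 0.05, while DESeq2 called 14 and limma voom 4. The smallest p belonged to Gli3 (log2 1.21 ± 0.24), Ablim1 (1.12 ± 0.25) and Btbd9 (1.20 ± 0.27), which failed the test with an adjusted p of 0.280. Nuclear OXPHOS had a median interaction of 0.57 and macrophage markers of 1.66, with camera adjusted p of 5.08e-14 and 0.000439, and an adjusted p = 0.796 for both with an estimated correlation. Mitochondrially encoded OXPHOS, fibroblast, clock, cardiac muscle, skeletal muscle, T cell, B cell, cytokine and mitochondrial proteostasis genes also had interactions above, and cell cycle genes below, those of other genes. Their camera adjusted p ran from 3.51e-05 to 0.0461, and the adjusted p = 0.796 with an estimated correlation. Adjusted over the list alone, 8 B cell, 8 skeletal muscle, 5 T cell, 3 cardiac and 1 proteostasis gene had a higher, and of clock genes 6 a higher and 2 a lower interaction. WT replicate 5 had scores of 8.11 for skeletal muscle, 6.39 for B cell and 4.87 for T cell markers. Without it camera no longer called skeletal muscle, whose direction turned, or T cell markers (adjusted p = 0.684 for both), B cell markers (0.462) or cytokines (0.248). The cytokine call ended without any 1 of 13 libraries, the cell cycle call without any 1 of 12 (up to 0.501, without WT-BAPN replicate 7), skeletal muscle 11, T cell 5, proteostasis 3 (up to 0.0938, without KI replicate 2), B cell 2 and cardiac muscle 2 (up to 0.0853, without WT-BAPN replicate 7). Of these 12 lists only nuclear and mitochondrially encoded OXPHOS, fibroblast and proteostasis genes were still called with covariates, where the others had 0.0630 to 0.781 and the T cell and B cell directions turned (0.675 and 0.781). The cardiac and skeletal muscle scores are themselves among the covariates, so the loss of their calls was built in. Without the 4 libraries the B cell, T cell, cell cycle, cytokine and skeletal muscle calls ended (0.185 to 0.572), and the same 5 with the mesothelium score as a covariate (0.0724 to 0.143). Across genes, which are not independent replicates, the BAPN effects of the 2 genotypes had a Pearson correlation of 0.292 (0.433 without WT replicate 5 and 0.188 without KI replicate 5), a Spearman correlation of 0.111 and a slope of 0.267, and 67.4% of the 873 genes called in WT had the same sign in KI. No call was shared, where independent lists would share 0.0344 rises and 0.108 falls.

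Of the 873 genes called for BAPN in WT, 83.8% had a KI minus WT difference on BAPN of the opposite sign. Both contrasts use the WT-BAPN libraries, which alone gives opposite signs: with KI-BAPN simulated as equal to WT-BAPN the share was 67.2% (64.9 to 69.5% over 40 simulated tables, which called a median of 1906 genes). With the WT-BAPN libraries split 4 and 3 it had a median of 74.6% and ran from 45.9 to 100% over 35 splits. These called 0 to 1484 genes, with a median of 66. The splits give no chance level like the simulation, since their contrasts share no WT-BAPN library. The covariance of the fold changes was -0.182, against -0.0808 simulated and -0.119 as the median of the splits.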

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

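The tests of the neuronal genes, of WT replicate 5 and of the knock-in genotype in this part were chosen after the results they bear on were seen, the others before.

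Single libraries stood far from the others of their group in 32 of 164 tests of a group, where chance gives about 1 in 20. WT replicate 5 held 14 of them. Its scores (mean log2 CPM) were 8.11 for skeletal muscle, 9.95 for airway epithelium, 6.39 for B cells, 4.87 for T cells, 3.18 for neutrophils, 5.28 for Schwann cells, 4.43 for chondrocytes, 2.44 for cell cycle and 4.58 for apoptosis genes. It was also highest in mitochondrial fatty acid synthesis at 4.55, and lowest in contractile genes at 8.69, elastic fibre at 5.59, TGF-beta at 5.55 and autophagy at 5.82. The neutrophil score rests on 4 genes, among them Ltf, which is named above with the genes of airway and gland epithelium. That score by itself therefore does not show neutrophil RNA. KI replicate 5 was apart in elastic fibre at 6.10, chondrocyte at -0.085, nuclear OXPHOS at 7.59, TCA cycle at 7.56, lipoylation at 5.49, fatty acid oxidation at 6.92, mitochondrial fatty acid synthesis at 4.92 and mitochondrial contacts at 5.97. The remaining ones were Atad3a in WT replicate 4 at 61.4 CPM, erythroid markers in KI replicate 3 at 1.72, contractile genes at 8.11 and T cell markers at 1.43 in KI-BAPN replicate 3, glycolysis in KI-BAPN replicate 2 at 7.03, sympathetic neuron genes in KI-BAPN replicate 5 at 1.57, chondrocyte markers in WT-BAPN replicate 5 at 3.54, interferon genes in WT-BAPN replicate 2 at 5.88, and lipoylation at 4.86 and fatty acid oxidation at 5.71 in WT-BAPN replicate 6.

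The 873 genes called for BAPN in WT were matched or passed by 3 of 100 splits of the same 13 samples, the real one included. This share is under the bound of 0.05 set before. A draw of 100 splits fixes it only roughly, and no adjustment was made over the comparisons, so chance is not firmly excluded. The highest other split called 1656 genes, and a split with more genes points to a structure among the samples. Other tissue in WT replicate 5 does not account for the whole: 74.7% of the called genes were still called without it. Both other explanations stay open too. If the WT libraries on plain water stood apart as a group, the called genes should move alike in KI against WT, but with the WT libraries split 3 and 3 the share of the same sign, at a median of 55.5%, ran from 0 to 100% over 20 splits that called 0 to 780 genes, so this test settles nothing. If BAPN were the cause in both genotypes the same sign should appear in KI, and 67.4% of genes had it, between the bounds set before.

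The fall of neuronal genes on BAPN in KI may reflect sympathetic nerve tissue in some KI libraries. Within groups, the mean of Rab3b, Syn2 and Omp, picked because they were called, correlated with the sympathetic neuron score at a Pearson r of 0.908 (permutation p = 0.0001) and a Spearman rho of 0.737 (permutation p = 0.0022), and r was 0.854 without the 2 libraries farthest from the median score. Th was at 238 CPM, Dbh at 334 CPM and Npy at 441 CPM in KI replicate 2, and each was under 5 CPM in every KI-BAPN library. The permutations repeated neither the choice of Rab3b, Syn2 and Omp nor that of the marker list, so their p-values lend no support. The correlation shows that neuronal genes varied together, and it cannot tell where the nerve RNA came from. No biological explanation was tested. The 5 calls of this comparison were matched by 8 of 100 splits, with 1018 genes in the highest other, so chance is not excluded.

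The higher OXPHOS values in KI on BAPN had a median of 0.71. With fat and muscle scores as covariates it was 0.41, and with offsets for gene length 0.49. Each lies between the bounds set before, so neither is excluded and neither is shown to be the cause. It was 0.52 without KI-BAPN replicate 3, 0.57 without KI-BAPN replicate 2 and up to 0.83 without other single libraries. KI-BAPN replicates 3 and 2 had the highest white adipocyte scores of their group, 8.89 and 7.51. They also had its highest nuclear OXPHOS scores, 7.81 and 7.64. The other KI-BAPN libraries had nuclear OXPHOS scores of 6.42 to 6.93, inside the WT-BAPN range of 6.06 to 6.97. If the genotype were the cause without BAPN, KI against WT on plain water should show it. The median there was 0.11, above 0 and below the bound, so the genotype stays open. KI replicate 5 stood apart in that group, with a nuclear OXPHOS score of 7.59 and a white adipocyte score of 9.08. The other KI libraries on plain water had nuclear OXPHOS scores of 6.50 to 6.67, against 6.57 to 6.97 in WT.

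For KI against WT on plain water, 7 of 100 splits called at least 27 genes, with 1001 in the highest other. On BAPN 5 of 100 splits called at least 1 gene, with 747 in the highest other. The splits alone do not exclude chance for these 2 counts. The 1 gene called on BAPN is Atad3a, at 231 to 1038 CPM in KI and at 24.9 to 44.8 CPM in WT (exact permutation p = 0.000583). These values argue against chance for that gene. For the interaction 100 of 100 splits called at least 0 genes, with 2701 in the highest other, but any split matches a count of 0, so this decides nothing about chance. Splits that called several times the real count point to a structure among the samples in these comparisons and in BAPN within KI. Atad3a itself has exact tests of its own.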

How the results depend on the processing

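The fit with edgeR's newer method, the mesothelium covariate, the length offsets (also with WT replicate 5 left out) and the fit without 4 libraries rich in other tissue were chosen after the data were seen. Atad3a kept its direction and its call in every alternative run, with log2 differences of 4.55 to 4.91 on plain water and 3.90 to 4.31 on BAPN over single libraries left out. The other counts moved with the settings, and the cause was not tested.

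For BAPN in WT (873) the count was 1524 without the 4 libraries, 1344 with length offsets and no WT replicate 5, 1493 with DESeq2, 4234 with limma voom, 433 at an absolute log2 change of at least 1 and 6 at an adjusted p under 0.01. Leaving out single libraries gave 327 to 1609: 327 without WT replicate 1, 404 without WT replicate 4, and 503, 375, 420, 351, 442 and 1609 without WT-BAPN replicates 2 to 7. For BAPN in KI (5) it was 0 with no filter, 123 with covariates, 0 with only the groups compared, 108 with the newer method, 3 with the mesothelium covariate, 3 (none of the 5) without the 4 libraries, 198 with DESeq2, 0 with limma voom and 0 at 0.01. Single libraries gave 0 to 143: 0 without KI replicate 2 or 5, 140 and 143 without KI replicates 3 and 4, 1 (none of the 5) without KI-BAPN replicate 2 and 0 without each other KI-BAPN library. For KI against WT on plain water (27) it was 7 with no filter, 274 with covariates, 8 with only the groups compared, 212 with the newer method, 73 with the mesothelium covariate, 1 without the 4 libraries, 480 with DESeq2, 271 with limma voom and 2 at 0.01. Single libraries gave 1 to 293: 2, 3, 2, 2, 293 and 6 without WT replicates 1 to 6, and 5, 1, 63 and 6 without KI replicates 1, 2, 4 and 5. On BAPN the count of 1 was 28 with DESeq2 and 3 with limma voom, and it was 1 without any single library. For the interaction it was 14 with DESeq2 and 4 with limma voom, and 0 without any single library.

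With the replicate number as a block the counts were 1024, 0, 29, 1 and 0 for BAPN in WT, BAPN in KI, KI against WT on plain water, on BAPN, and the interaction. The 1024 held 616 of the 873 genes of the main fit. The 29, of which 8 were higher and 21 lower, held 15 of the 27. Samples that share a number correlated at -0.521 to 0.571, so the numbers do not pair the samples, and 1, 0, 0 and 2 samples correlated best with their own number for BAPN in WT, BAPN in KI, and KI against WT on BAPN and on plain water.

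The correlation of the BAPN effects (0.292) was 0.348 with the stricter filter and 0.360 with covariates, and 0.188 to 0.433 over single libraries, lowest without KI replicate 5 and highest without WT replicate 5. The share of opposite signs (83.8%) was 80.8% with covariates, 74.6% with the WT-BAPN libraries split, and 75.1 to 89.2% over single libraries.

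Of 65 list calls all 65 were lost with an estimated correlation and 64 with fry. The call kept with fry was collagen and fibrosis for BAPN in WT (fry adjusted p = 0.0259). With fat and muscle covariates 32 were lost and 5 turned, with the mesothelium covariate 10 were lost, and without the 4 libraries 20 were lost and 2 turned. The calls lost or turned with fat and muscle covariates include those of fat and muscle lists, whose scores are the covariates. For these lists the loss was built in and decides nothing. Without the 4 libraries fewer KI samples on plain water remain, which can end a call too. Over single libraries left out, a call was kept 818 times, lost 106 times and turned 1 time. The replicate block ended 10 calls, length offsets 7 and the fit of only the groups compared 2. The direction turned with covariates, at adjusted p of 0.728 for interferon genes on BAPN in KI, 0.912 for interferon genes in KI against WT on plain water, 0.458 for white adipocytes in KI against WT on BAPN, and 0.675 for T cells and 0.781 for B cells in the interaction. It turned without the 4 libraries for lysosome genes on BAPN in KI at 0.580 and for skeletal muscle in the interaction at 0.572, the latter also without WT replicate 5 at 0.684, in a range from 0.00886 (without WT replicate 6) to 0.684 over single libraries. At 13127645 to 26490651 counts per library, 51 of 100 simulated genes changed by 1 log2 unit were recovered for BAPN in WT, and 17 of 100 for the interaction.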

Other observations

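The genes and terms of this part were chosen after their values were seen. The small heat shock protein Hspb1 was at 624 to 3420 CPM in the WT libraries on plain water and at 85.8 to 862 CPM in the other 18. It fell on BAPN in WT by 3.09 ± 0.50 on the log2 scale, with an edgeR adjusted p of 0.00696, which it shared with 4 other genes as the smallest of that comparison, among them the HSP90 cochaperone Ahsa1. The chaperone Hsp90aa1 fell there by 1.83 ± 0.32. In KI against WT on plain water Hspb1 was at -2.05 ± 0.54 and Hsp90aa1 at -1.48 ± 0.36, neither passing the test. The heat shock score ran from 7.83 to 9.25 in the WT libraries and from 6.36 to 8.18 in the others. The mean mesothelium score of WT-BAPN minus WT was 0.58 (exact permutation p = 0.664) and that of KI-BAPN minus KI 1.02 (exact permutation p = 0.474), so neither passed. The mesothelium genes Msln, Krt19, Muc16 and Upk1b were among the 6 highest loadings of the first principal component, which held 35.05% of the variance and was highest in WT replicate 5. In WT-BAPN replicates 2 and 5 the mesothelium score was 3.29 and 4.06 and the macrophage score 5.24 and 5.35, the highest of that group for both.

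Among the annotated terms, cytoplasmic translation had a median of -0.47 over 82 genes for BAPN in WT (camera adjusted p = 1.4e-14) and of 0.65 for KI against WT on BAPN (camera adjusted p = 5.96e-31). Protein refolding had a median of -0.87 over 20 genes for BAPN in WT. For BAPN in KI, monocyte chemotaxis had a median of 2.02 over 23 genes. Of 2016 terms 88, 160, 182, 115 and 127 passed in the 5 comparisons in order, and 0 in each with an estimated correlation.

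The BAPN effect in WT and the genotype effect on plain water share the WT libraries. Their fold changes had a Pearson correlation of 0.469 across genes. It was 0.494 in simulations without any effect and had a median of -0.184 over 20 splits of the WT libraries. The Spearman correlation was 0.481, against 0.451 simulated and 0.104 as the median of the splits. The covariance was 0.338, against 0.0978 simulated and -0.145 split. The sign of the split values thus depends on the measure. Any split also puts WT replicate 5, rich in other tissue, into a single contrast. Its part in the sign was not tested, so no opposed effect is read from the negative values. The calls shared 4 rises and 6 falls. Independent lists share 0.482 and 0.351, which leaves out the common WT libraries, and the simulations, which leave out any effect, shared 0 and 0. With the WT libraries split 3 and 3 the median was 0 and 0 and the highest 1 and 4, so no shared effect is read from these calls.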
